A study of Homo sapiens with 8 samples.

How the data were processed

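Chromatin immunoprecipitation with a pan-acetyl-lysine antibody followed by sequencing was applied to 8 libraries of U2OS cells, an osteosarcoma line that here carries AsiSI-ER-AID, a restriction enzyme fused to an oestrogen receptor domain so that 4-hydroxytamoxifen (4-OHT) brings it into the nucleus, where it cuts its 8-base sites. Per the labels, 6 libraries came from cells given 500 nM 4-OHT for 4 h and 2 from untreated cells. The groups, as the labels give them, were WT without and with 4-OHT, PDHE1α without and with 4-OHT, and 4 further 4-OHT libraries labelled WT, C2A, H2A and C2H2A. The labels do not spell out what was done to PDHE1α, the E1α subunit of the pyruvate dehydrogenase complex that makes acetyl-CoA from pyruvate, nor what C2A, H2A and C2H2A stand for, and the names are used as given. The further WT-labelled 4-OHT library is called the second WT library below. Each group held 1 library, so there were no replicates, and no p-value across libraries was computed.

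Per the labels' protocols, sonicated nuclei were immunoprecipitated, libraries were made with a tagmentation-type kit and 25 cycles of PCR, and fragments of about 250 bp were cut from a gel. Per the submitters' processing notes, read quality was inspected with FastQC 0.11.4, reads were aligned with Bowtie2 2.2.6 and peaks were called with MACS2 2.2.1, in lists deposited separately for each library. PCR copies were not marked with molecular identifiers in any source used here, so intervals below cover counting error only.

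Per the file headers, each deposited list gives the pileup of a peak, a coverage signal counting the fragments that overlap its summit, and the fold enrichment, the authors' ratio of that pileup to a local background. The headers of 2 further deposited columns were damaged, and their values were identified as −log10 of the p-value and −log10 of the q-value. In 99.9% to 100% of the peaks of a list, the deposited −log10 p-value was within 0.02 of the Poisson tail computed from the pileup and the background that the fold enrichment implies. The deposited peak width is a length in bases. All these values are the authors', and fold enrichment is used only to describe and rank peaks within a list. In 100% of peaks the implied background was at least the peak's own fragments spread over 10 kb, the form MACS2 takes from the immunoprecipitated library itself. An input library was not used here.

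Per the submitters' processing notes the build was hg19, but 572 of the 194224 peaks, on 8 chromosomes, lay beyond the ends of hg19 chromosomes. Set on the RefSeq gene table of GRCh38.p14, 12.8% of all summits lay within 1 kb of an end of a protein-coding gene, against 3.01% and 3.0% after the peaks were moved 500 kb down or up. The peak positions were therefore read as GRCh38 and are given as in the lists. The gene table held gene starts, ends and names without strand, so a start of transcription could not be told from a gene's other end, and exons could not be told from introns. A gene was counted as carrying a peak where a listed peak reached within 1 kb of either gene end, and a summit as near a gene end within 1 kb. Genome sequence was not used here. AsiSI sites were therefore not analysed here, and random gene lists were matched on the decile of gene length in place of promoter GC content. These are departures from the design fixed before the data were examined.

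Peaks on chromosomes 1 to 22 and X were analysed. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Libraries were compared in 10 pairs by peak number, by overlap of at least 1 bp in both directions, by location, and by the 19974 protein-coding genes with a peak. Shares carry exact (Clopper-Pearson) 95% intervals. Chance overlap was taken from 20 shuffles of peak positions within chromosomes. A peak with at least 6 fragments at its summit is called a strong peak. For 9 gene lists fixed before the data were examined, the number of members with a peak was set beside 10000 random lists of the same size, as a percentile that describes these libraries. All members of the 9 lists were found in the gene table. Genes were named by a rule fixed at the same time: for each pair up to 10 genes of highest fold enrichment with a peak in 1 library and none in the other, each way, and up to 4 members of each list with the highest fold enrichment in either library. Genes outside this rule are marked as chosen after their values were seen. The text prints part of the genes that the rule names, and 1 of the others was left out on purpose and is not reported here.

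Read totals were not in the sources used here, so depth was taken from the lists. Implied backgrounds were whole multiples of 1 fragment per 10 kb, within 0.06 of a step, for 87.3% to 97.8% of those inspected, and the step gave the mean fragment length (86.6 to 187 bases). The lowest background of a list then gave the genome-wide depth in fragments per 10 kb. In the libraries without 4-OHT the lowest background was 2 fragments per 10 kb, the least a listed peak can have, which is an upper bound. Depth there was estimated from peaks of 2 fragments, as the ratio of those with 1 further fragment within 10 kb to those with none, 513 to 932 for WT and 235 to 208 for PDHE1α. Where the lowest background was also usable, it hid the classes with the fewest further fragments. The estimator was there taken from the next 2 classes, 1 further fragment apart, with their ratio scaled by the Poisson model. The ratio of 1 further fragment to none was therefore not itself checked. This scaled estimator gave 2.02 against 2.11 in PDHE1α with 4-OHT, 2.49 against 2.36 in C2H2A, 2.6 against 3.25 in H2A and 9.49 against 9.24 in WT with 4-OHT. In C2A it gave 0.29 against 6.13. There the class with more further fragments had a −log10 p-value of 3.74, short of the 3.77 that its list reached, so most of that class was not listed. Both classes passed in the other libraries named here and in both libraries without 4-OHT (5.06 against 4.97 in WT, 5.24 against 5.04 in PDHE1α). The intervals of the depth estimates cover counting error only. Ratios were therefore also taken with the depths without 4-OHT divided by 0.8, the lowest ratio of estimate to lowest background among libraries whose classes passed, an alternative added after the data were seen, as were ratios at the upper bound of those depths. To compare lists at matched depth, summit fragments of the deeper library were thinned at random to the depth of the shallower library, and peaks were kept that still reached the smallest −log10 p-value of the shallower list, over 20 draws. This comparison was added after the data were seen. So was a measure of strong regions: of the merged regions listed in all 6 libraries with 4-OHT, the 100 with the highest median of summit fragments per unit of depth over these libraries were taken, and a region that a library did not list counted as 0. On simulated data of 60000 sites, the depth estimator gave 0.551 for a true 0.55 and 1.1 for a true 1.1 fragments per 10 kb. The simulated further fragments followed the Poisson model that the estimator assumes, so the model itself was not tested. Thinning from 9 fragments per 10 kb gave 0.982, 0.978 and 0.997 times the simulated sites called at 0.55, 1.1 and 2.1. Only true sites were counted, so listed peaks that rest on background were not covered. Thinning from 11 gave 0.987, 1 and 0.993 times the simulated sites called at 6.1, 3.3 and 2.4, the depths of C2A, H2A and C2H2A. All simulated libraries had the same fragment length, which the libraries did not. Matched depth was therefore repeated with the background, or the background and the summit fragments, rescaled to the fragment length of the shallower library, also added after the data were seen.

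Alternatives fixed before the data were examined were stricter lists (−log10 q-value of at least 10, or fold enrichment of at least 5), lists of equal length (1581 peaks in all 8 libraries, or 18083 in the 6 with 4-OHT), a window of 500 bp at gene ends, stricter overlap, all contigs, and random lists that were not matched. Lists at matched depth and peaks anywhere in a gene were added later.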

Results

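Lysine acetylation on chromatin was mapped by ChIP-seq (chromatin immunoprecipitation and sequencing) with a pan-acetyl-lysine antibody in 8 libraries, 1 for each group. The cells were U2OS, an osteosarcoma line, with AsiSI-ER-AID, a restriction enzyme that enters the nucleus and makes DNA breaks when 4-hydroxytamoxifen (4-OHT) is given. The design asks where acetylation lies after induced DNA breaks, and whether that changes with PDHE1α, the pyruvate dehydrogenase subunit, or in cells labelled C2A, H2A or C2H2A. There were no replicates, so each difference is between single libraries. Peaks and their fold enrichments are those of the MACS2 lists, and fold enrichments rank peaks within a list only. Without 4-OHT the lists held 3193 peaks in the WT library and 1581 in the PDHE1α library. With 4-OHT they held 54147 peaks in WT, 18083 in PDHE1α, 39745 in the second WT library, 33573 in C2A, 25088 in H2A and 18814 in C2H2A. Background depth, in fragments per 10 kb, was 9.24 in WT with 4-OHT, 2.11 in PDHE1α with 4-OHT, 11.02 in the second WT library, 6.13 in C2A, 3.25 in H2A and 2.36 in C2H2A. Without 4-OHT it was estimated at 0.55 (95% interval 0.49 to 0.61) in WT and 1.13 (0.93 to 1.37) in PDHE1α. Depth and peak number therefore fell in almost the same order among the 6 libraries with 4-OHT, and WT with 4-OHT alone stood out of that order.

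**Figure D1:**
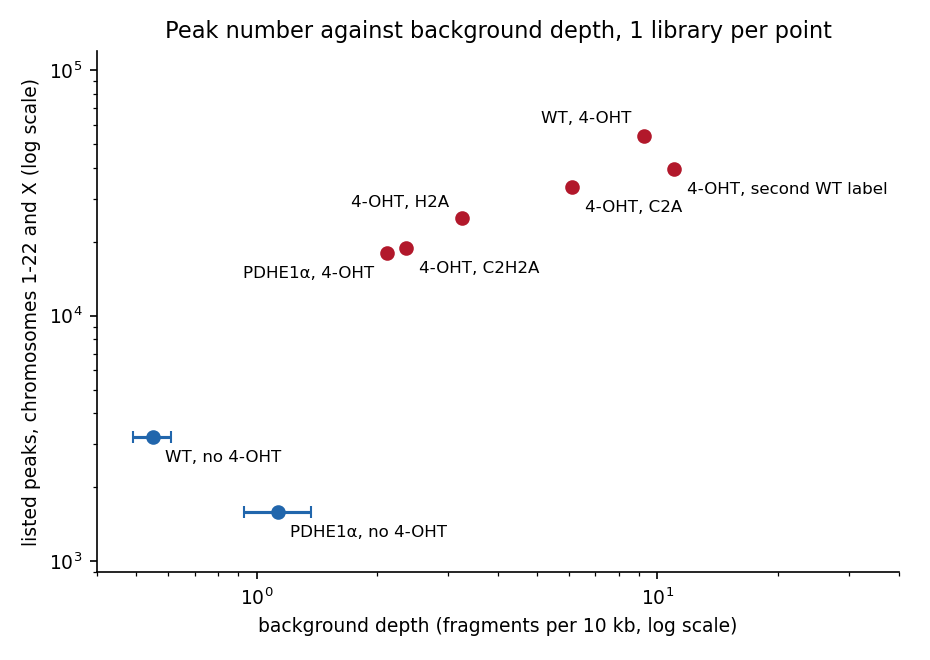
Listed peaks on chromosomes 1 to 22 and X (y axis, log scale) against background depth in fragments per 10 kb (x axis, log scale), 1 point per library, red with 4-OHT and blue without. Bars are 95% intervals of the depth estimate, drawn for the libraries without 4-OHT. The deepest library, the second WT library, had 39745 peaks and the shallowest with 4-OHT, PDHE1α, had 18083.

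Acetyl-lysine peaks lay both at genes and between them. In WT with 4-OHT, 11.1% of summits (10.8% to 11.3%) were within 1 kb of an end of a protein-coding gene, against 2.5% of shuffled peaks, and 44.0% were inside gene bodies, against 42.4% of shuffled peaks. The share near gene ends was 12.5% in PDHE1α with 4-OHT, 16.7% in the second WT library, 13.7% in C2A, 12.3% in H2A and 10.7% in C2H2A. It was 6.7% (5.8% to 7.6%) in WT and 5.8% (4.7% to 7.0%) in PDHE1α without 4-OHT. The peaks of smallest p were the least often at gene ends. When the WT list with 4-OHT was divided by p into 5 equal parts, 3.7% of summits in the part of smallest p were near a gene end (3.4% to 4.1%), against 15.8% (15.1% to 16.5%) in part 4. The highest fold enrichments of WT with 4-OHT were at chromosome ends, 75.7 at X:156030467-156030739, 72.9 at 22:50807907-50808465 and 71.9 at 5:10352-10612 (GRCh38), and these regions had peaks in all 8 libraries. Among the next highest was a peak inside CAMKMT, a calmodulin methyltransferase gene, at 2:44572548-44572801, with 48.5, chosen after its values were seen.

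Ribosomal protein genes were the list most often marked. Of 34 members, 27 had a peak at a gene end in WT with 4-OHT, 33 in the second WT library, 31 in C2A, 29 in H2A, 24 in PDHE1α and 18 in C2H2A, each at percentile 100 of random lists. Housekeeping genes followed in WT, with 19 of 30, also at percentile 100. Genes of other tissues, such as liver, muscle or epithelial genes, had a peak in 3 of 30 members in WT with 4-OHT, at percentile 0.8, and mesenchymal and bone-lineage genes in 6 of 18, at percentile 57.6. In PDHE1α with 4-OHT these lists were at percentiles 40.3 and 95.2. PDHA1, which encodes PDHE1α and belongs to the pyruvate dehydrogenase list, had no peak at either end in any of the 8 libraries and was singled out after its values were seen.

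**Figure D2:**
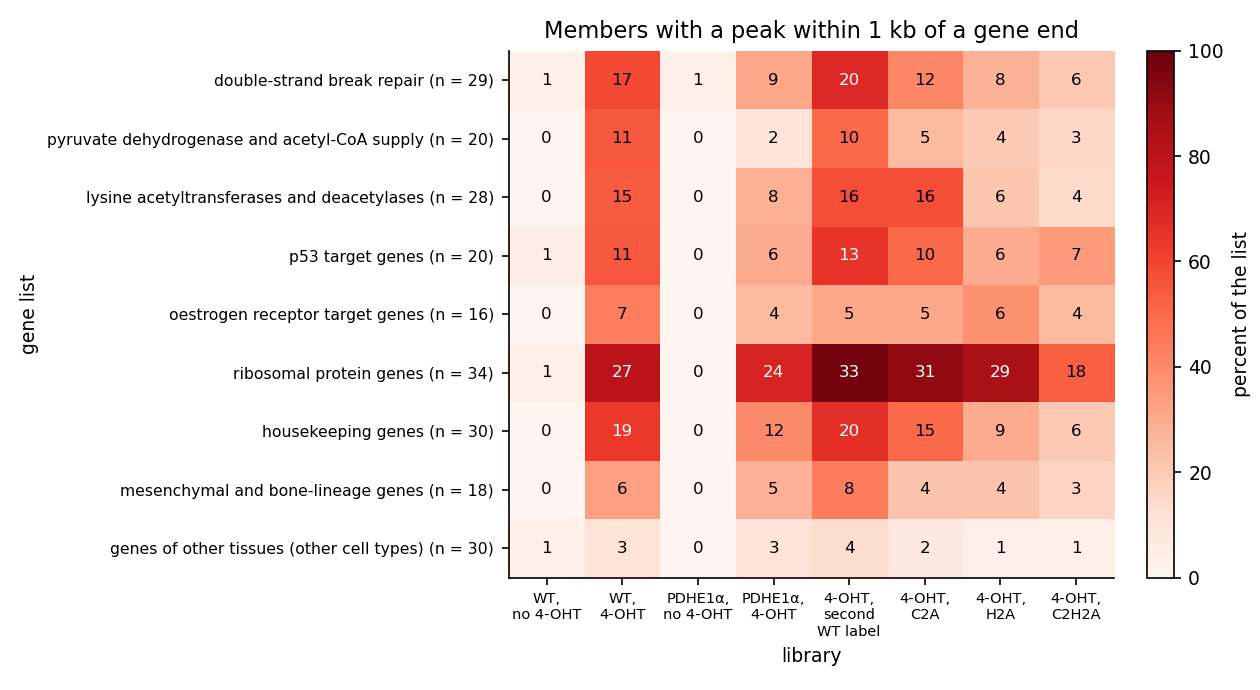
Numbers of list members with a peak within 1 kb of a gene end (figures in the cells) and their percent of the list (colour), for 9 fixed gene lists (rows) and 8 libraries (columns). Ribosomal protein genes ranged from 18 to 33 of 34 in the libraries with 4-OHT and were 1 or 0 in those without.

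In WT cells, 4-OHT was accompanied by peaks at many more genes. At an end of 6173 of 19974 protein-coding genes (30.9%) a peak was listed with 4-OHT, and of 255 (1.3%) without, with 168 genes in common. Of 29 genes of double-strand break repair, 17 had a peak with 4-OHT (percentile 99.7) and 1, NBN, a subunit of the break-sensing MRN complex, without. The 4 with the highest fold enrichment with 4-OHT were XRCC6 (10.0 at 22:41621045-41621304) and XRCC5 (8.06), which encode the Ku proteins that bind broken DNA ends, DCLRE1C (9.64), an end-processing nuclease, and PALB2 (8.33), a partner of BRCA2. A high percentile was not particular to repair genes, since ribosomal protein and housekeeping genes were at percentile 100 in this library. At matched depth, by the estimate of 0.55, the difference in number between the WT libraries was smaller. For peaks 2.15 times as many as without 4-OHT remained, in place of 16.96 times, and for genes 2.19 times, in place of 24.21. At the upper bound of that depth, 2 fragments per 10 kb, 6.44 times as many peaks remained. Of the 3193 WT peaks without 4-OHT, 45.3% rested on 2 fragments, and 1853 were listed in no library with 4-OHT. Listed peaks that rest on background would lower these ratios, and thinning was checked on true sites only. How much of the difference depth accounts for is therefore not settled. Most sites were not shared at matched depth. Of the thinned peaks 8.7% were in the list without 4-OHT, and of that list 18.9% were among the thinned peaks.

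Metabolic and acetylation genes of WT cells also had more listed peaks with 4-OHT than without. Of 20 genes of pyruvate dehydrogenase and acetyl-CoA supply, 11 had a peak with 4-OHT (percentile 97.9) and 0 without. In the other libraries with 4-OHT this list was at percentile 82.9 in second WT, 66.2 in C2H2A, 60.1 in H2A, 43.6 in C2A and 32.9 in PDHE1α. The members with a peak in WT included MPC2 (11.03), part of the mitochondrial pyruvate carrier, PDHX (8.06) and DLD (6.96), components of the pyruvate dehydrogenase complex, and ACLY (6.78), which makes acetyl-CoA from citrate. Of 28 lysine acetyltransferases and deacetylases, 15 had a peak with 4-OHT and 0 without, among them HDAC2 (18.7 at 6:113971218-113971525), HDAC7 (11.4), EP300 (10.6) and KAT5 (9.7), an acetyltransferase that acts in break repair. Of 20 p53 target genes, 11 had a peak with 4-OHT, led by XPC (16.7), a damage sensor of nucleotide excision repair, and PPM1D (9.63), a phosphatase that dampens the damage response. Only TP53I3 had one without 4-OHT. Of 16 oestrogen receptor targets 7 had a peak with 4-OHT (percentile 85.4) and 0 without, led by MYC (18.7 at 8:127743106-127743256) and XBP1 (12.8). Thinned to the depth without 4-OHT, the WT 4-OHT library kept a peak in a median of 1.5 repair genes (0 to 4 over the draws), 0.5 acetyl-CoA genes (0 to 2) and 5 ribosomal protein genes (1 to 8), where 1, 0 and 1 were listed without 4-OHT. The thinned library kept 2 acetyltransferases and deacetylases (1 to 4), 2 p53 targets (0 to 4) and 1 oestrogen receptor target (0 to 3), beside 0, 1 and 0.

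Among all genes, the highest fold enrichments found with 4-OHT and not without were at DDX59 (30.8), an RNA helicase gene, SCIN (30.8), which encodes an actin-severing protein, and NCOR1 (27.7), a corepressor that recruits histone deacetylases. Listed without 4-OHT and not with it were 87 genes, led by ATG16L1 (13.4 at 2:233296533-233296687), an autophagy gene, POLR2L (7.78), an RNA polymerase subunit gene, and KLHDC9 (7.27), and including EGR1 (5.71), an immediate early transcription factor. Of the 3193 WT peaks without 4-OHT, 36.6% (34.9% to 38.3%) overlapped a peak found with 4-OHT, against 0.66% when shuffled, and of its 713 strong peaks 67.2% (63.6% to 70.6%). The ratio of peak numbers depended on which library stood for 4-OHT: thinned to the depth of WT without 4-OHT, the second WT library kept 1.02 times the peaks of that library (1.39 or 0.68 with fragment length rescaled), and over the 6 libraries the ratio ranged from 1.02 to 2.39 (0.68 to 3.1 with fragment length rescaled). At the upper bound of that depth, 2 fragments per 10 kb, the ratio was 6.44 for WT and 3.49 for the second WT library.

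In the PDHE1α libraries the gain with 4-OHT was seen beyond depth. Peaks rose in number 11.44 times as listed and 8.0 times at matched depth (6.97 to 8.73 over the interval of the depth estimate). Genes with a peak numbered 2579 with 4-OHT and 109 without, 23.66 times as many as listed and 14.97 times at matched depth. Ribosomal protein genes had a peak in 24 of 34 members with 4-OHT, in a median of 19 after thinning (15 to 21 over the draws), and in 0 without. Housekeeping genes had 12 of 30, 6 after thinning (4 to 11) and 0 without, and p53 target genes 6 of 20, 5 after thinning (2 to 6) and 0 without. RPL5 (13.8), RPL37 (12.6), RPS23 (10.9), HSP90AB1 (14.3), an abundant chaperone gene, TP53I3 (10.7), PPM1D (8.43), HDAC2 (8.78) and XBP1 (16.8) were among the members with a peak with 4-OHT and none without.

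In PDHE1α with 4-OHT, repair genes were at percentile 98.8 of random lists and acetyl-CoA genes at percentile 32.9. Of 29 repair genes, 9 had a peak in PDHE1α with 4-OHT, 4 after thinning (2 to 6), led by MDC1 (6.58) and CHEK2 (6.2), an adaptor and a kinase of the break response. Without 4-OHT the repair gene listed was XRCC6 (5.46), which had no peak in PDHE1α with 4-OHT. Of 20 acetyl-CoA genes, MPC2 (6.15) and ACLY (5.66) had a peak with 4-OHT, and 0 without. Outside the lists, the highest fold enrichments found with 4-OHT and not without were at F2RL2 (20.9), LPAR5 (20.7), both receptor genes, KRT80 (20.1), a keratin gene, and NQO1 (19.9 at 16:69726932-69727093), a quinone reductase of the oxidative stress response. RAD17 (18.2), which loads a checkpoint clamp at damaged DNA, shared its peak with its neighbours AK6 and TAF9. In the other direction 51 genes were listed, led by PICK1 (7.73) and COPS4 (6.94). Of the 1581 peaks without 4-OHT, 63.6% (61.1% to 65.9%) were found with 4-OHT, and of its 516 strong peaks 96.1% (94.1% to 97.6%).

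**Figure D3:**
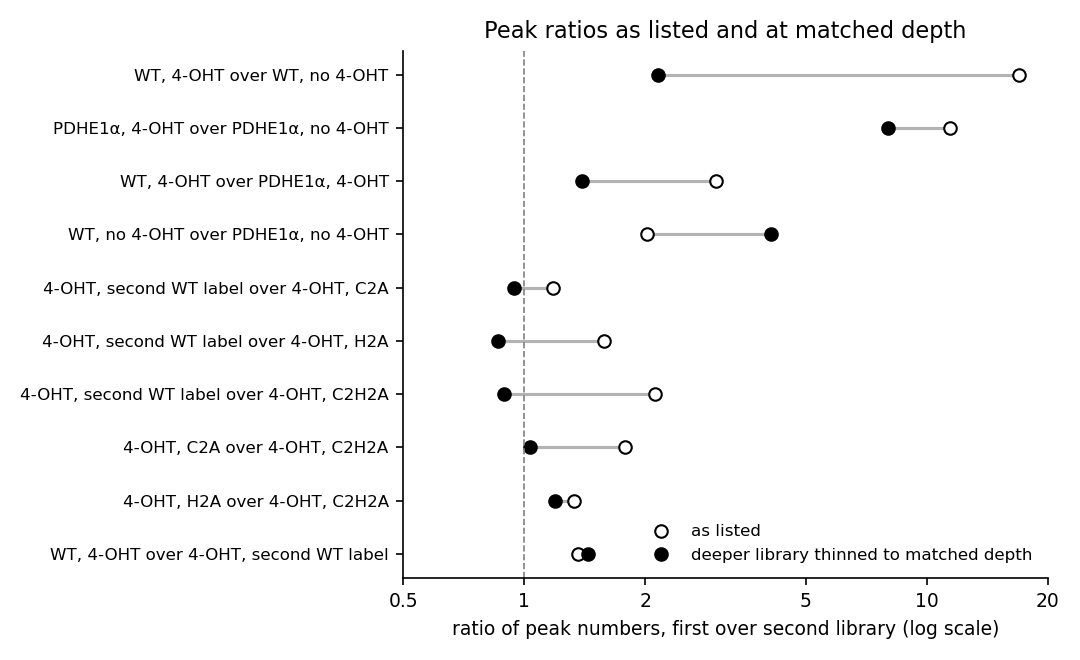
Ratio of peak numbers for 10 pairs of libraries (x axis, log scale), as listed (open circles) and with the deeper library thinned to the depth of the shallower (filled circles). WT with over without 4-OHT moved from 16.96 to 2.15, and PDHE1α with over without 4-OHT from 11.44 to 8.0.

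The strongest regions were read against the same depth estimates. The 100 regions with the most summit fragments for the depth of the 6 libraries with 4-OHT, chosen after their values were seen, included regions at MICAL2, FRYL, LDLRAD3 and ARHGAP32, and 39 of them overlapped a protein-coding gene. Also among them were chromosome-end regions, 22:50807907-50808465, 5:10346-10612 and X:156030467-156030739. Without an input library, whether the signal there reflects acetylation was not tested. Over the 100 regions, the median number of summit fragments without 4-OHT was 9 in WT and 10 in PDHE1α. In WT, the median was 19.8 summit fragments per unit of depth with 4-OHT and 16.4 without (14.7 to 18.2 over the depth interval), a ratio of 0.83. In PDHE1α it was 28.5 with 4-OHT and 8.9 without (7.3 to 10.7), a ratio of 0.31. With depth without 4-OHT raised by its largest calibration error, these ratios were 0.66 and 0.25, and at the upper bound of depth 0.23 and 0.18, so the contrast between WT and PDHE1α rests on the depth estimates. The other libraries with 4-OHT lay between 15.1 (second WT) and 29.4 (C2H2A), with the lower values in the deeper libraries, so each ratio depends on the library it is set against. Of the 100 regions, 76 were listed in WT without 4-OHT and 87 in PDHE1α without 4-OHT. Regions that were not listed counted as 0. The regions were picked in libraries with 4-OHT, which favours those libraries in both contrasts.

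**Figure D4:**
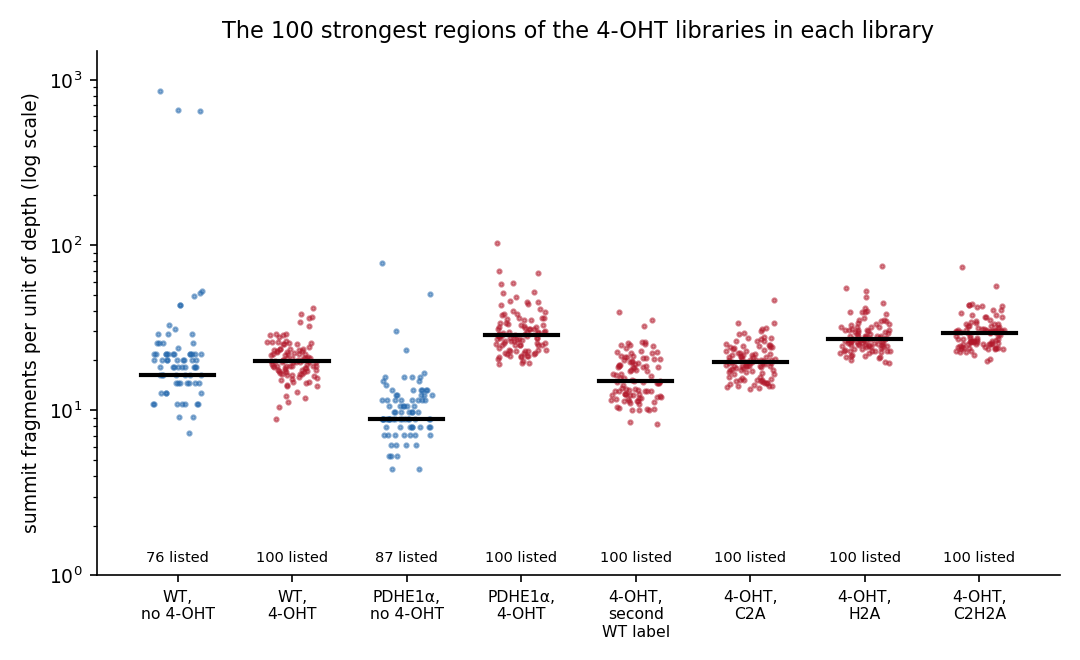
Summit fragments per unit of depth (y axis, log scale) at the 100 strongest regions of the 4-OHT libraries, 1 point per listed region, in each of 8 libraries (red with 4-OHT, blue without). Black lines are medians over all 100 regions, 16.4 and 19.8 for WT without and with 4-OHT and 8.9 and 28.5 for PDHE1α.

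With 4-OHT, fewer genes carried a peak in PDHE1α than in WT, 2579 against 6173, and 2115 were in common. Repair genes with a peak were 9 against 17, acetyl-CoA genes 2 against 11, acetyltransferases and deacetylases 8 against 15, p53 targets 6 against 11 and ribosomal protein genes 24 against 27. XRCC5, DCLRE1C, PDHX, DLD, PLK3 (9.07 in WT), HSPA8 (8.72) and ITGB1 (7.19) had a peak in WT and none in PDHE1α. MYC (18.7 and 6.51), HDAC2 (18.7 and 8.78), XPC (16.7 and 7.33) and XBP1 (12.8 and 16.8) had a peak in both, each value being the fold enrichment of its own list. At matched depth WT had 1.02 times the genes of PDHE1α, in place of 2.39 times, and 1.39 times the peaks, in place of 2.99 times. The 2 WT-labelled libraries with 4-OHT differed from each other by 1.43 times at matched depth. With the background rescaled to fragment length, WT had 1.44 times the peaks of PDHE1α and the WT-labelled libraries differed by 1.38 times, and with background and summit fragments rescaled 1.26 and 1.82 times. The second WT library thinned to the depth of PDHE1α kept 0.84 times its peaks (1.15 or 0.45 with fragment length rescaled).

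Group by group, thinning WT to the depth of PDHE1α left a peak in a median of 9 repair genes (5 to 12 over the draws) beside 9 in PDHE1α, 7 acetyltransferases and deacetylases (4 to 10) beside 8, 5 p53 targets (3 to 8) beside 6, and 4.5 acetyl-CoA genes (2 to 6) beside 2. Ribosomal protein genes had 17 (15 to 20) in thinned WT and 24 in PDHE1α. Found in WT and not in PDHE1α with the highest fold enrichment were FUT8 (20.8), a fucosyltransferase gene, CALM3 (20.1), a calmodulin gene, and FGF2 (19.3), a growth factor gene. The other way, 464 genes were led by DALRD3 and NDUFAF3, which shared a peak (11.6 at 3:49021358-49021465), LBX2 (10.4), CCNQ (9.66) and NR1D2 (9.3), a circadian nuclear receptor gene. Of the PDHE1α peaks, 86.3% (85.8% to 86.8%) were found in WT.

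Without 4-OHT, the WT and PDHE1α lists shared few genes and more of their strong peaks. Of the 109 genes of PDHE1α, 7 were among the 255 of WT, and 19.2% (17.3% to 21.3%) of PDHE1α peaks overlapped a WT peak, against 0.02% when shuffled. Of the strong PDHE1α peaks 44.0% (39.7% to 48.4%) were found in WT, and of the strong WT peaks 29.2% in PDHE1α. ATG16L1 (13.4), IFNAR1 (13.1), an interferon receptor gene, and STARD9 (10.8) led the genes found in WT and not in PDHE1α, and PICK1 (7.73), MTMR4 (7.29) and COPS4 (6.94) those found in PDHE1α and not in WT. In the 9 lists, WT had a peak at NBN (2.89), TP53I3 (4.7), RPS16 (2.93) and MBP (2.93), and PDHE1α at XRCC6 (5.46). The WT library had 2.02 times the peaks of the PDHE1α library. At matched depth by the estimates it had 4.11 times, and with its depth at the upper bound 1.02 times, so neither the order of depth nor the size of this ratio is settled. In WT without 4-OHT, 45.3% of peaks rested on 2 fragments, and in PDHE1α 28.3%.

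Among the 4-OHT libraries labelled second WT, C2A, H2A and C2H2A, genes with a peak numbered 7352, 5010, 3384 and 2285. Repair genes with a peak fell in the same order, 20, 12, 8 and 6 of 29, and so did housekeeping genes, 20, 15, 9 and 6 of 30. Acetyltransferases and deacetylases had 16, 16, 6 and 4 of 28, and acetyl-CoA genes 10, 5, 4 and 3 of 20. The order was not kept by p53 targets, 13, 10, 6 and 7 of 20, or oestrogen receptor targets, 5, 5, 6 and 4 of 16. BRCA2 (9.72 in the second WT library), the recombination mediator, and PDHX (7.33) had a peak in the second WT library and in none of C2A, H2A and C2H2A. XRCC6, TP53I3, PPM1D, XPC, KAT5, HDAC7, XBP1, MYC, SIAH2, RPL5 and RPL37 had a peak in all 4. EP300 (11.7 in the second WT library, 7.65 in C2A, 4.19 in H2A) and HDAC2 (10.8, 10.3 and 9.82) had none in C2H2A.

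The mean fragment was 187.4 bases in the second WT library, 132.5 in C2A, 92.5 in H2A and 88.2 in C2H2A, so depth was not their only difference. Thinned to the depth of each library, the second WT library kept 0.94 times the peaks of C2A, 0.86 times those of H2A and 0.89 times those of C2H2A, where the listed ratios were 1.18, 1.58 and 2.11. With the background also rescaled to fragment length the ratios were 1.04, 1.09 and 1.19, and with background and summit fragments rescaled 0.82, 0.53 and 0.49. Its genes with a peak were 1.15, 1.1 and 1.21 times theirs, where the listed ratios were 1.47, 2.17 and 3.22. Its repair genes became a median of 16 beside 12 in C2A, 11 beside 8 in H2A and 7 beside 6 in C2H2A, with draws from 12 to 18, 7 to 15 and 4 to 12. Its acetyltransferases and deacetylases became 12 (9 to 14) beside 16 in C2A, 8 (5 to 12) beside 6 in H2A and 7 (4 to 9) beside 4 in C2H2A. Its ribosomal protein genes became 31.5 (30 to 33) beside 31 in C2A, 23.5 (21 to 29) beside 29 in H2A and 19.5 (16 to 26) beside 18 in C2H2A. These gene ratios and list numbers were not rescaled to fragment length. Median peak width was 369 bases in the second WT library, 221 in C2A, 145 in H2A and 137 in C2H2A. A wider peak can reach a gene end more easily, and that effect was not tested. Of the peaks of C2A, H2A and C2H2A, 75.5%, 76.2% and 79.3% were found in the second WT library.

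Some genes were listed in C2A, H2A and C2H2A and not in the second WT library. PIP5K1A, a lipid kinase gene, had fold enrichments of 11.2, 18.7 and 16.8 in these 3 libraries, TXNRD3, a thioredoxin reductase gene, 13.9, 15.7 and 14.9, and FOSL2, an AP-1 transcription factor gene, 8.08, 10.5 and 13.7. All 3 genes also had a peak in WT with 4-OHT (24.5, 20.7 and 13.8). In the second WT library and missing from C2H2A were PSMD7 (17.9), a proteasome subunit gene, SLC25A32 (16.7), a mitochondrial carrier gene, and GLRX (14.6), a glutaredoxin gene, which was also missing from H2A. UFM1 (14.3), a ubiquitin-like modifier gene, was missing from C2A.

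Set beside C2H2A, which joins the names of both other labels, C2A had 1.78 times the peaks as listed and 1.03 times at matched depth (1.15 or 0.79 with fragment length rescaled), and H2A 1.33 and 1.19 times. Ribosomal protein genes with a peak were 29 in H2A, a median of 29 after thinning to C2H2A (26 to 29 over the draws), and 18 in C2H2A. Thinned C2A had 21 (16 to 24). RPL23 (15.02) led the genes found in H2A and not in C2H2A, and HOXC10 (11.8), a homeobox gene, those found in C2H2A and not in H2A. SLC25A32 with DCAF13 (18.1) and FTL (15.4), the ferritin light chain gene, led the genes found in C2A and not in C2H2A, and UFM1 (13.8) and ARFGEF1 (10.8) those found in C2H2A and not in C2A. Of the C2H2A peaks, 71.6% were found in C2A and 70.0% in H2A.

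The WT-labelled libraries with 4-OHT gave a measure of how far libraries of a like label lay apart. Genes with a peak were 6173 in WT and 7352 in the second WT library, with 4801 in common, and 68.1% (67.6% to 68.5%) of the peaks of the second WT library were found in WT. Repair genes with a peak were 17 and 20 with 14 in common, and ribosomal protein genes 27 and 33 with 27 in common. PIP5K1A, TXNRD3, EXT1 (17.9) and SOX9 (13.8) were listed in WT alone of the pair, and FTL (13.4), GDF5 (11.3) and CHUK (11.2) in the second WT library alone. The mean fragment was 100 bases in WT and 187 in the second WT library, and the median peak width 174 and 369 bases. Whether the labels mean the same cells is not stated in the sources used here.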

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

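The tests of depth, of fragment length, of immunoprecipitation strength and of the share of narrow peaks were chosen after the results were seen, and the tests of median width and of listing in PDHE1α without 4-OHT for the private strong peaks were set down before.

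Mitochondrial peaks numbered 5 in PDHE1α with 4-OHT and 3 without, a higher count in data no comparison used, and the difference was not tested. In WT the count went the other way, 4 with 4-OHT and 9 without. By the depth estimates, summit fragments of the mitochondrial peaks per unit of depth were lower with 4-OHT in PDHE1α, 37.97 against 59.3, and in WT, 7.8 against 1099.14. These are totals over unequal numbers of peaks. In PDHE1α without 4-OHT the total was 67 fragments, which at the upper bound of depth, 2 fragments per 10 kb, falls below 37.97 per unit. The order of the PDHE1α totals is therefore not settled. Median peak width rose by 34 bases with 4-OHT in WT (a change of 34) and moved by -12 in PDHE1α, opposite directions in the 2 label pairs, and the difference was not tested.

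More peaks were listed with 4-OHT than without, in WT and in PDHE1α. For PDHE1α, lower depth as the whole cause is argued against: 8.0 times as many peaks remained at matched depth (6.97 to 8.73, and 7.28 to 8.97 with fragment length rescaled), 4.11 to 8.29 times over the 6 libraries with 4-OHT (2.42 to 9.43 with fragment length rescaled), and the depth without 4-OHT would have to be at most 0.17 (0.4 for the second WT library), against an estimate of 1.13, for 1.5 times or less to remain. For WT, depth and a change in acetylation cannot be told apart, since 2.15 times as many peaks remained for WT (6.44 at the upper bound of the depth without 4-OHT) but 1.02 times (3.49) for the second WT library. The untreated WT library also had an excess at chromosome ends and in mitochondrial DNA, which remained at the upper bound of its depth. Whether that excess bears on its depth estimate was not tested, so the estimate stays uncertain. Weaker immunoprecipitation without 4-OHT also cannot be told apart from lower acetylation, since 96.1% of the strong PDHE1α peaks and 67.2% of the strong WT peaks without 4-OHT were sites of the 4-OHT library, and no spike-in or input was used here. An effect of the breaks or of 4-OHT itself stays open, untested.

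Fewer peaks were listed in PDHE1α, C2A, H2A and C2H2A than in the WT-labelled library beside them. For C2A, H2A and C2H2A, depth cannot be told apart from other differences: the second WT library thinned to each kept at most 0.94 times their peaks, but up to 1.19 times with the background rescaled to fragment length, which differed between them. For PDHE1α, depth cannot be told apart from a change with its label: WT kept 1.39 times its peaks, the second WT library 0.84 times, and the WT-labelled libraries differed by 1.43 times (1.44 against 1.38 with the background rescaled, 1.26 against 1.82 with summit fragments also). Fewer acetylated sites with the PDHE1α label stays open as untested, and changes at single genes with the C2A, H2A or C2H2A labels were not tested.

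Strong peaks of WT without 4-OHT were often missing from all libraries with 4-OHT, 177 of 713 (24.8%) against 6 of 516 (1.2%) for PDHE1α without 4-OHT. Stacked copies of single fragments were predicted to make them narrower, but their median width was 1.14 times that of the shared strong peaks. Of them 24.9% (18.7% to 31.9%), against 35.6% (31.6% to 39.9%) of the shared ones, were narrower than the mean fragment. They were thus not narrower as a set, but a stack is as wide as its fragment, so width cannot exclude copies of longer fragments. Stacked copies stay open, also for single narrow peaks, among them 4 of the 10 of highest fold enrichment. Acetylation common to untreated cells would place these peaks in PDHE1α without 4-OHT as well, where 0.6% of them and 38.6% of the shared strong peaks were listed. That does not decide the question, since which of these libraries is the deeper is not settled. The shared peaks were also picked for being listed in other libraries, which favours their being found again. The PDHE1α label differs between these libraries, so acetylation particular to untreated WT cells stays open, untested.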

How the results depend on the processing

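The tests at matched depth, including the raised depth and the rescaled fragment length, and those with a peak anywhere in a gene were chosen after the data were seen, and the other alternatives were fixed before the data were examined. No paired test was run, since each group holds 1 library and only WT and PDHE1α have a library with and without 4-OHT. Depth limits the ratios between libraries, several of which moved by over 1.5 times at matched depth, and depth without 4-OHT is an estimate. With that depth raised by its calibration error, the PDHE1α ratio with over without 4-OHT stayed within 1.5 times of the listed one (8.92). Not run were all alternatives for AsiSI sites, the distance profile around them, a promoter from 2 kb before to 500 bp after a transcription start, and matching on promoter GC decile, since genome sequence and strand were not used here. All contigs left 10 of 10 ratios of peak numbers within 1.5 times, and a window of 500 bp at gene ends left 10 of 10 gene ratios within 1.5 times and 9 of 9 list shares in WT within their intervals. Unmatched random lists changed the percentiles only, not the numbers of members. At each of the stricter thresholds 8 of 10 ratios of peak numbers stayed within 1.5 times. In the values that follow, libraries are with 4-OHT unless stated, and the cause of the changes was not tested. Gene ratios in lists of equal length are no measure of direction, even where they fall on the other side of 1, because the part of a list that is kept differs between libraries, and in WT the peaks of smallest p lay least often at gene ends. In some pairs both lists are cut to a small part, and why their ratios fell was not tested.

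At a −log10 q-value of at least 10, the ratio of peak numbers was 145.65 for WT over WT without 4-OHT and 73.11 for PDHE1α over PDHE1α without 4-OHT. The ratio of genes with a peak was 392 for WT over WT without 4-OHT, 315 for PDHE1α over PDHE1α without 4-OHT, 4.98 for WT over PDHE1α, 4 for WT without 4-OHT over PDHE1α without 4-OHT, 2.51 for second WT over C2A and 5.68 for second WT over C2H2A. The lists without 4-OHT held only 139 peaks in WT and 65 in PDHE1α at this threshold, few of them near a gene end. Gene ratios that involve these lists rest on very few genes and do not measure the size of a change. The share of peaks found in the other library was 50.4% for WT without 4-OHT in WT, 96.9% for PDHE1α without 4-OHT in PDHE1α, 97% for PDHE1α in WT, 32.3% for PDHE1α without 4-OHT in WT without 4-OHT, 91.6% for C2A in second WT, 85% for H2A in second WT, 89.3% for C2H2A in second WT, 85.9% for C2H2A in C2A, 85.3% for C2H2A in H2A and 83.1% for second WT in WT. The share of summits near a gene end was 2.9% in WT without 4-OHT, 6.7% in WT, 1.5% in PDHE1α without 4-OHT, 5.7% in PDHE1α, 10.5% in second WT, 6% in C2A, 6.2% in H2A and 4.5% in C2H2A. The share of members with a peak in WT was 10.3% for repair, 5% for acetyl-CoA supply, 17.9% for acetyltransferases and deacetylases, 20% for p53 targets, 50% for ribosomal proteins, 20% for housekeeping and 0% for mesenchymal.

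At a fold enrichment of at least 5, the ratio of peak numbers was 39.08 for WT over WT without 4-OHT and 1.31 for WT without 4-OHT over PDHE1α without 4-OHT. In shallow lists this threshold is mainly one on the number of summit fragments, so these ratios depend on depth. The ratio of genes with a peak was 133.83 for WT over WT without 4-OHT, 57.65 for PDHE1α over PDHE1α without 4-OHT and 1.3 for WT without 4-OHT over PDHE1α without 4-OHT. These gene ratios also rest on few genes, since the lists without 4-OHT held 908 peaks in WT and 692 in PDHE1α. The share of peaks found in the other library was 66.5% for WT without 4-OHT in WT, 92.2% for PDHE1α without 4-OHT in PDHE1α, 93.9% for PDHE1α in WT, 32.8% for PDHE1α without 4-OHT in WT without 4-OHT, 87.4% for C2A in second WT, 81.5% for H2A in second WT, 84.6% for C2H2A in second WT, 82.1% for C2H2A in C2A, 81.5% for C2H2A in H2A and 76.1% for second WT in WT. The share of summits near a gene end was 2.9% in WT without 4-OHT, 10.5% in WT, 2.6% in PDHE1α without 4-OHT, 10.2% in PDHE1α, 16.2% in second WT, 12.2% in C2A, 10.4% in H2A and 8.3% in C2H2A. The share of members with a peak in WT was 30% for acetyl-CoA supply and 32.1% for acetyltransferases and deacetylases.

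At matched depth, the ratio of peak numbers was 2.15 for WT over WT without 4-OHT, 1.39 for WT over PDHE1α, 4.11 for WT without 4-OHT over PDHE1α without 4-OHT, 0.94 for second WT over C2A, 0.86 for second WT over H2A, 0.89 for second WT over C2H2A and 1.03 for C2A over C2H2A. The ratio of genes with a peak was 2.19 for WT over WT without 4-OHT, 14.97 for PDHE1α over PDHE1α without 4-OHT, 1.02 for WT over PDHE1α, 5.48 for WT without 4-OHT over PDHE1α without 4-OHT, 1.1 for second WT over H2A, 1.21 for second WT over C2H2A and 1.15 for C2A over C2H2A. The share of peaks found in the other library was 18.9% for WT without 4-OHT in WT, 58.9% for PDHE1α without 4-OHT in PDHE1α, 66.3% for PDHE1α in WT, 28.1% for PDHE1α without 4-OHT in WT without 4-OHT, 68.1% for C2A in second WT, 57.1% for H2A in second WT, 53% for C2H2A in second WT, 59.2% for C2H2A in C2A, 67.3% for C2H2A in H2A and 70.3% for second WT in WT. With WT thinned to the depth of PDHE1α, the share of members with a peak in WT was 31% for repair, 22.5% for acetyl-CoA supply, 25% for acetyltransferases and deacetylases, 25% for p53 targets, 50% for ribosomal proteins and 31.7% for housekeeping.

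At matched depth with the background rescaled to fragment length, the ratio of peak numbers was 1.91 for WT over WT without 4-OHT, 7.28 for PDHE1α over PDHE1α without 4-OHT, 1.44 for WT over PDHE1α, 4.38 for WT without 4-OHT over PDHE1α without 4-OHT, 1.19 for second WT over C2H2A and 1.15 for C2A over C2H2A.

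With background and summit fragments rescaled, the ratio of peak numbers was 2.7 for WT over WT without 4-OHT, 1.26 for WT over PDHE1α, 3.6 for WT without 4-OHT over PDHE1α without 4-OHT, 0.82 for second WT over C2A, 0.53 for second WT over H2A, 0.49 for second WT over C2H2A and 0.79 for C2A over C2H2A.

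At matched depth with the depth without 4-OHT raised by its calibration error, the ratio of peak numbers was 2.68 for WT over WT without 4-OHT.

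In lists of 1581 peaks, the ratio of genes with a peak was 0.21 for WT over WT without 4-OHT, 0.53 for PDHE1α over PDHE1α without 4-OHT, 0.36 for WT over PDHE1α, 0.92 for WT without 4-OHT over PDHE1α without 4-OHT, 1.48 for second WT over C2H2A, 0.89 for C2A over C2H2A, 0.95 for H2A over C2H2A and 0.32 for WT over second WT. The share of peaks found in the other library was 29.5% for WT without 4-OHT in WT, 32.6% for PDHE1α without 4-OHT in PDHE1α, 68.6% for PDHE1α in WT, 77.9% for C2A in second WT, 65.9% for H2A in second WT, 63.8% for C2H2A in second WT, 72.9% for C2H2A in C2A, 77.5% for C2H2A in H2A and 66.5% for second WT in WT. The share of summits near a gene end was 5.3% in WT without 4-OHT, 0.9% in WT, 2.8% in PDHE1α, 2.9% in second WT, 1.8% in C2A, 2.1% in H2A and 2.1% in C2H2A. The share of members with a peak in WT was 0% in each of the 9 lists.

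In lists of up to 18083 peaks, the ratio of genes with a peak was 4.91 for WT over WT without 4-OHT, 0.49 for WT over PDHE1α, 1.26 for second WT over H2A, 1.29 for second WT over C2H2A, 1.04 for C2A over C2H2A and 0.45 for WT over second WT. The share of peaks found in the other library was 30.3% for WT without 4-OHT in WT, 64.3% for PDHE1α in WT, 81.8% for C2A in second WT, 71.4% for H2A in second WT, 66.8% for C2H2A in second WT, 65.4% for C2H2A in C2A, 65.3% for C2H2A in H2A and 68.9% for second WT in WT. The share of summits near a gene end was 5.9% in WT, 12.5% in second WT, 10.6% in C2A and 10.7% in H2A. The share of members with a peak in WT was 6.9% for repair, 5% for acetyl-CoA supply, 14.3% for acetyltransferases and deacetylases, 15% for p53 targets, 50% for ribosomal proteins, 10% for housekeeping and 0% for mesenchymal.

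With 50% of the peak required to be covered, the share of peaks found in the other library was 34.3% for WT without 4-OHT in WT, 58.4% for PDHE1α without 4-OHT in PDHE1α, 84% for PDHE1α in WT, 16.3% for PDHE1α without 4-OHT in WT without 4-OHT, 74.3% for C2A in second WT, 74.2% for H2A in second WT, 77.3% for C2H2A in second WT, 69.6% for C2H2A in C2A, 65.9% for C2H2A in H2A and 34.7% for second WT in WT.

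With peak centres within 500 bp, the share of peaks found in the other library was 39.3% for WT without 4-OHT in WT, 66.6% for PDHE1α without 4-OHT in PDHE1α, 88.5% for PDHE1α in WT, 74% for C2H2A in C2A, 72.8% for C2H2A in H2A and 70.3% for second WT in WT.

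With a peak anywhere in the gene, the share of members with a peak in WT was 79.3% for repair, 75% for acetyltransferases and deacetylases, 85% for p53 targets, 75% for oestrogen receptor targets, 77.8% for mesenchymal and 40% for other tissues.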

Other observations

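All tests and values in this part were chosen after the data were seen.

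The private strong peaks of WT without 4-OHT lay near a gene end in 2.8% of cases, and its shared strong peaks in 2.4%. Those with the highest fold enrichment were at 2:64864609-64864731 (19.4, 26 summit fragments, narrower than the mean fragment) and 4:58875424-58876257 (13.5, 29), with ATG16L1 (13.4), TXNRD2 (12.5), a mitochondrial thioredoxin reductase gene, and VPS72 (10.5), a subunit of histone-exchange complexes, within 1 kb of others.

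Chromosome ends took far more fragments for their depth in WT without 4-OHT than in any other library. At 5:10346-10612 it had 471 summit fragments, where WT with 4-OHT had 335, and 855.7 per unit of depth, where the other 7 libraries had 27.1 to 69.3. At 22:50807907-50808465 it had 659.5 against 35.1 to 103, and at X:156030467-156030739 643.1 against 30.1 to 57.9. Set against the upper bound of its depth, 2 fragments per 10 kb, these 3 regions still had 235.5, 181.5 and 177. In mitochondrial DNA, 3 regions were listed in all 8 libraries. WT without 4-OHT had 198 summit fragments at MT:16055-16543, where the other libraries had 30 to 45, 89 at MT:3080-3970, against 10 to 26, and 59 at MT:80-566, against 10 to 18. At the upper bound of its depth these were 99, 44.5 and 29.5 per unit of depth, where the other libraries, by their own depth, had at most 31.9, 12.4 and 15.

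Merged over all libraries, the peaks formed 76066 regions, of which 8385 were listed in all 6 libraries with 4-OHT, 303 in all 8 and 48.5% in exactly 1. Of the 8385 regions, 10.0% were listed in WT and 11.5% in PDHE1α without 4-OHT.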
